A study of Mus musculus with 6 samples.

How the data were processed

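RNA from mouse cerebral cortex was sequenced in 6 libraries, 3 from mice given a scrambled shRNA and 3 from mice given an shRNA against Fabp7. Both shRNAs were delivered by an AAV-PHP.eB vector, a capsid that crosses the blood-brain barrier in mice, under a promoter of Gfap, a gene of astrocytes. Per the labels' protocols, the vector was given at 21 days of age, lipopolysaccharide (LPS, a bacterial cell wall component that sets off inflammation) was injected weekly 3 times at 1 mg/kg from 4 months of age, and tissue was taken 24 h after the last dose. Libraries came from 0.5 µg of total RNA with a stranded mRNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The count column of each deposited file is headed by another number, whose meaning is not given in the sources used here and which was not used. The labels do not say that each sample is a separate animal, so p-values measure the spread between these samples.

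The deposited files hold raw read counts per gene, with no normalization, in the layout of featureCounts, per the file headers. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, DESeq2 and the build GRCm39, with no role or order. The gene positions in the files did not follow that build: of 49056 gene IDs found in the GENCODE M21 annotation of GRCm38, 44858 (91.4%) had the same chromosome, start and end. Coordinates are printed as the files give them and are read as GRCm38. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. Of the 49315 genes in the files, 48970 had a symbol in the reference table, and the other 345 took 0.0991% to 0.114% of the counts of a library. Counts per library ranged from 16914012 to 18991235, and genes with few counts carry the larger errors.

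Genes were filtered with filterByExpr, which left 17185, and libraries were scaled by TMM factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, model with the group alone), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are shFabp7 minus shScr, and each SE is the log2 fold change divided by the square root of the F statistic. Levels are CPM (counts scaled to a common library size) after TMM scaling, as mean ± SD over 3 libraries.

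A total of 45 gene lists (pathways and cell type markers) were fixed before the data were examined, and the 43 with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera compares a list with all other genes. It was run again with the correlation estimated for each list, and fry was run as a test of each list by itself. All tests were two-sided. For each list, members past the threshold were also counted when adjusted over the list alone.

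The rule for named genes, also fixed before the data were examined, took Fabp7, then up to 12 genes per direction that passed the threshold, had groups that did not overlap, a mean of at least 1 CPM and a full gene symbol. For each list described, it took up to 4 members past the threshold, or the 2 with the highest mean expression where none passed. Any other member named was chosen after its values were seen. A few list members are not reported here.

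The scripts were tested on simulated counts drawn from the means and library sizes of these libraries, with 200 of 17185 genes changed in each of 5 runs. For shFabp7 against shScr, edgeR recovered 49.3% of genes changed 1.5-fold, 75.2% of those changed 2-fold and 95.8% of those changed 4-fold, and 8.38% of its calls were false. DESeq2 recovered 52.5%, 76.7% and 95.8%, with 14.4% of its calls false. With the interferon list shifted by -0.5 (log2), camera called that list and 0 others. Genes were simulated independently, so this does not test camera on lists whose members vary together. The simulation also held no differences of sex, region or library shared by many genes. The shares recovered and false may therefore not hold for the real libraries, where Fabp7 at a log2 fold change of -2.31 did not pass in edgeR. In the real data the estimated correlation was 0.37 for the interferon list.

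No library was a copy of another: the chi-square per degree of freedom between pairs ranged from 6.32 to 36.3, and Pearson correlations of log2 CPM across genes from 0.970 to 0.990. Sex is not in the labels and was read from Xist against Y-linked genes. Alternatives tried were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 samples, limma-voom with quality weights, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, each library left out in turn and, for lists, a prior count of 0.5. Added after seeing the data were sex as a covariate, a regional score as a covariate (the mean log2 CPM of hippocampal, striatal and thalamic or hypothalamic markers minus that of excitatory neuron markers), and shScr libraries 1 and 3 left out together. Of 58 named genes checked for exons shared with another gene, 19 had such an overlap. Among them, Cxcl10, Junb and Fabp3 shared 5.9%, 7.5% and 9.8% of their exon sequence with Art3, Prdx2 and Zcchc17 on the opposite strand. These partners had 439, 15785 and 4257 reads over all libraries, against 357, 5094 and 4770 for the named genes, whose values are therefore uncertain.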

Results

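The cortex of LPS-treated mice was compared between 3 libraries with a scrambled shRNA (shScr) and 3 with an astrocyte-directed shRNA against Fabp7 (shFabp7). The series has the response of astrocytes to endotoxemia as its subject. All 6 libraries came from mice given LPS, so the comparison is between the shRNA groups under LPS, and the effect of LPS itself was not measured. Total counts were 17789433, 18760154 and 18105596 in shScr libraries 1 to 3, and 16966118, 16914012 and 18991235 in shFabp7 libraries 1 to 3.

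Fabp7, which encodes the brain fatty acid-binding protein of astrocytes and radial glia, was lower in all 3 shFabp7 libraries than in any shScr library. Its gene lies on chromosome 10 from 57784881 to 57788450 on the plus strand (ENSMUSG00000019874). The libraries held 484, 285 and 290 Fabp7 reads in shScr and 93, 41 and 66 in shFabp7. Mean levels were 19.1 ± 6.27 CPM and 3.86 ± 1.56 CPM (SD, n = 3 each), which left 20.2% of the shScr level. The log2 fold change was -2.31 with an SE of 0.35, and its adjusted p of 0.0704 by edgeR's quasi-likelihood test did not pass the threshold. DESeq2 gave an adjusted p of 3.41e-12, and the exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 allows. Fabp5 and Fabp3, the other family members with enough counts to test, had log2 fold changes of 0.01 ± 0.09 (SE) and 0.17 ± 0.10 (SE), and neither passed the threshold. Both were named after their values were seen, and the sign of the Fabp5 value turned with the setting. The Fabp3 value ranged from 0.017 to 0.23 over the alternatives.

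**Figure D1:**
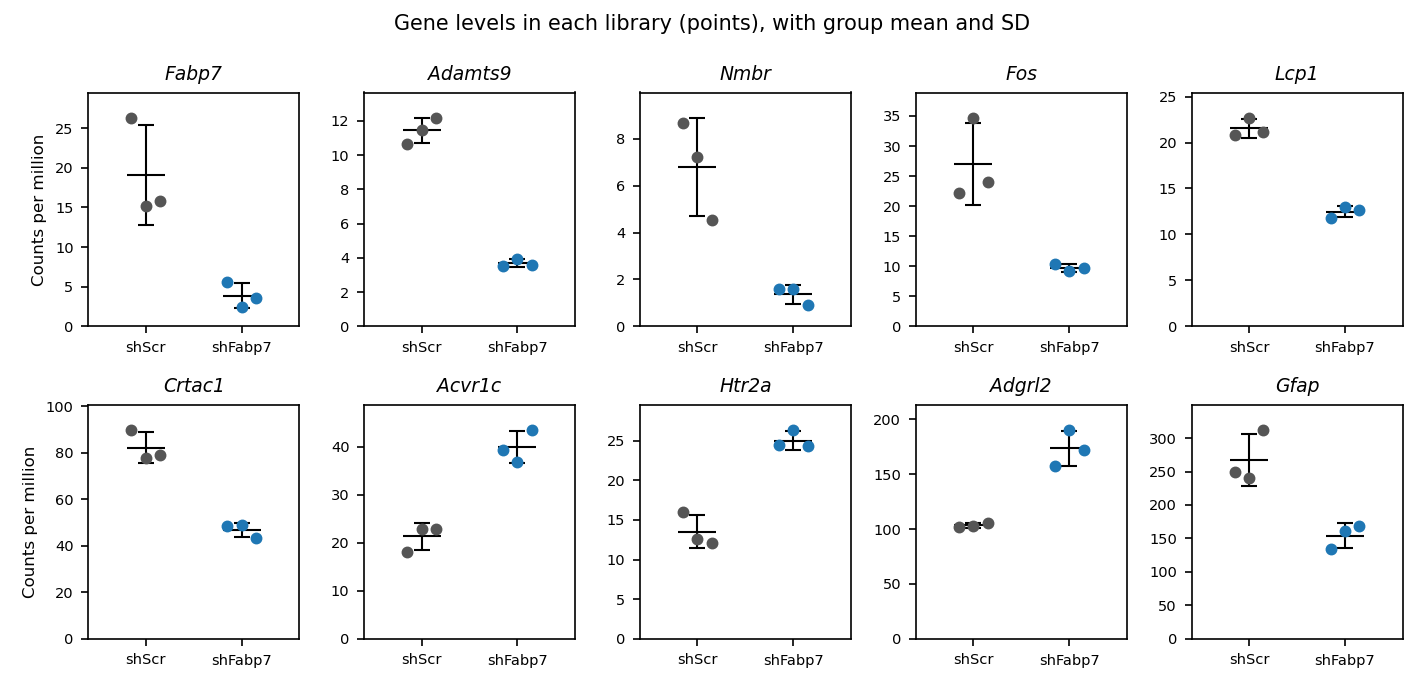
Levels of 10 genes in CPM (vertical axes, each starting at 0) in the 3 shScr and 3 shFabp7 libraries; points are libraries, horizontal bars the group mean and whiskers 1 SD. Fabp7 averaged 19.1 CPM in shScr and 3.86 CPM in shFabp7, and for each gene drawn the values of the groups do not overlap.

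Across the genome, 20 genes differed between the groups, 10 higher and 10 lower in shFabp7. Nmbr, the neuromedin B receptor, fell by 2.32 on the log2 scale, from 6.81 ± 2.09 to 1.37 ± 0.399 CPM (SD, n = 3 each). Adamts9, a secreted metalloprotease encoded on chromosome 6 from 92772699 to 92943492 (ENSMUSG00000030022), fell by 1.63 (SE 0.14), from 11.4 ± 0.753 to 3.69 ± 0.233 CPM, and had the lowest adjusted p of all genes tested (0.00699). Fos, an immediate-early transcription factor, fell by 1.46, from 27.0 ± 6.79 to 9.77 ± 0.645 CPM. Ust, a sulfotransferase of dermatan and chondroitin sulfate, and Crtac1, a secreted calcium-binding protein, had log2 fold changes of -0.98 and -0.81. Sik1, a salt-inducible kinase, Lcp1, an actin-bundling protein of leukocytes, Tenm3, a teneurin of synaptic wiring, and Adcy8, a calcium-stimulated adenylyl cyclase, had values of -0.79, -0.79, -0.76 and -0.68. The tenth gene, Gm19744, lay outside the naming rule and was named after its values were seen. It fell by 1.58 and shares 114 bp of exon sequence with Tenm3 on the opposite strand.

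The 10 genes that rose had log2 fold changes from 0.41 to 0.90. Acvr1c, an activin receptor of the TGF-beta family encoded on chromosome 2 from 58267453 to 58357895 (ENSMUSG00000026834), rose from 21.3 ± 2.77 to 39.9 ± 3.33 CPM (SD, n = 3 each), a log2 fold change of 0.90 with an SE of 0.11. Htr2a, a serotonin receptor of cortical pyramidal neurons, rose from 13.5 ± 2.11 to 25.003 ± 1.15 CPM, and Adgrl2, an adhesion receptor of synapses, from 103 ± 1.995 to 173 ± 16.2 CPM. The sialyltransferase gene St6gal2 and the BTB-domain gene Btbd17 each had a log2 fold change of 0.69. Klhl29 had 0.66, Scube1, which encodes a secreted and cell-surface protein, 0.61, and the zinc finger gene Zbtb40 0.59. Shc3, a neuronal signalling adaptor, had 0.52, and Ppp1r10, a nuclear regulator of protein phosphatase 1, had 0.41. Adjusted p-values of the 20 genes in edgeR ranged from 0.00699 to 0.0455, and all 20 also passed in DESeq2.

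DESeq2 called 699 genes, 386 higher and 313 lower. In edgeR, 2880 genes had an unadjusted p under 0.05, where 859 would be reached by chance on average. The groups did not overlap for 3934 genes (22.9%, against 10% by chance on average). Genes vary together, so a single split can lie far from these averages. The unadjusted number was 1383 with the regional score and 3865 with 1 surrogate variable. The number of genes called rested on single libraries. It was 0 without shFabp7 library 2 or 3 and 10 without shFabp7 library 1. It was 182 without shScr library 1 and 900 without shScr library 2. Without shScr library 3 it was also 20, but only 9 of these were among the 20 called with all libraries. With sex as a covariate 7 genes passed, with the regional score 9, and without shScr libraries 1 and 3 together 89. That last comparison sets 1 shScr library against 3, so its spread comes from the shFabp7 libraries alone and the lone shScr library is assumed to vary like them.

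**Figure D2:**
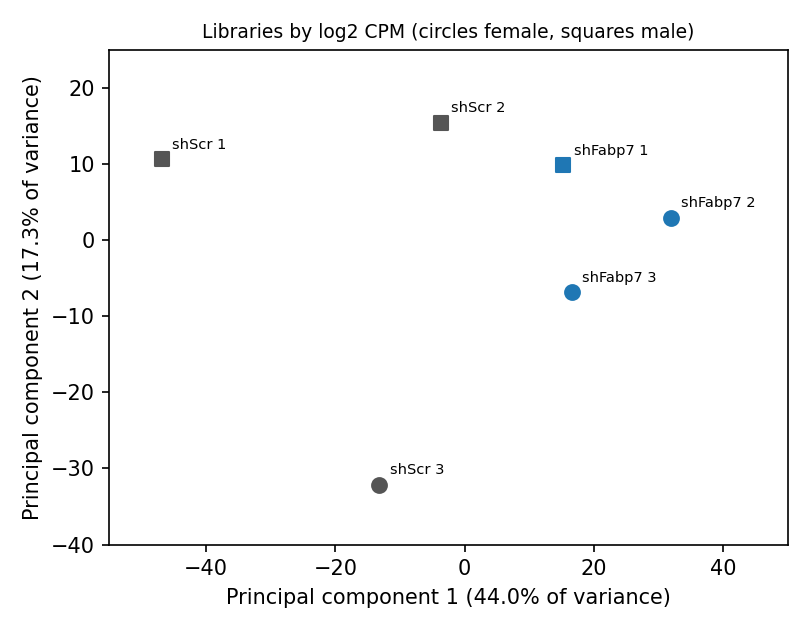
Principal component 1 (horizontal, 44.0% of the variance of log2 CPM) against principal component 2 (vertical, 17.3%) for the 6 libraries. Gray is for shScr and blue for shFabp7, with circles for libraries read from the counts as female and squares for male. The shFabp7 libraries lie between 15.3 and 31.9 on component 1 and the shScr libraries between -46.9 and -3.65, with shScr library 1 farthest from the rest.

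Of 3 lists of reactive astrocyte genes, camera called the pan-reactive and A1-type lists lower in shFabp7 at its preset correlation (adjusted p = 0.433 for both with an estimated correlation) and did not call the A2-type list, which had a median of -0.06, a mean of -0.24 and an adjusted p of 0.329. The pan-reactive astrocyte list, genes induced in astrocytes by many insults, had a median log2 fold change of -0.61, with 10 of 13 members below 0. Gfap, the intermediate filament gene of astrocytes, averaged 267 ± 39.1 CPM in shScr and 154 ± 18.1 CPM in shFabp7 (SD, n = 3 each), a log2 fold change of -0.79 with an SE of 0.12. Vim, another filament gene, had -0.13, with a range of -0.29 to -0.048 over the alternatives. Serpina3n, a serine protease inhibitor, had -0.64, Cp, which encodes ceruloplasmin, -0.62, and the chemokine gene Cxcl10 -1.24. These 4 (Gfap, Serpina3n, Cp and Cxcl10) were lower when adjusted over the list alone and in DESeq2, and 0 of the 13 passed over all genes tested. Camera gave the list an adjusted p of 0.0102, and adjusted p = 0.433 with an estimated correlation. The A1-type list, astrocyte genes induced by LPS, had a median of -0.40 with 10 of 12 members below 0. Its camera adjusted p was 0.0123, and adjusted p = 0.433 with an estimated correlation. Its most highly expressed members, Fkbp5 and H2-D1, had log2 fold changes of 0.27 and -0.07, the sign of H2-D1 turning without shScr library 2. No member passed over all genes or when adjusted over the list alone, and the proteasome gene Psmb8 had -0.51.

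Cytokine and chemokine genes had a median of -0.44, with 10 of 15 members below 0 (camera adjusted p of 0.0266, and adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, 4 were lower and 2 higher, and 0 passed over all genes tested. Il1b, which encodes interleukin-1 beta, had 43 reads in the 3 shScr libraries and 3 in the 3 shFabp7 libraries. That ratio was 13.4 after scaling, with a 95% exact counting interval of 4.29 to 67.6 that covers counting error only. The monocyte chemoattractant genes Ccl12 and Ccl2 had log2 fold changes of -1.94 and -1.78. Over the alternatives they ranged from -2.28 to -1.77 and from -2.52 to -1.19, with Ccl2 tested in 16 of the 17. In DESeq2, 1 member of the list was lower and 1 higher. The higher pair was Cxcl12 at 0.38 and Cx3cl1, a neuronal chemokine, at 0.29. The NF-kB list had a median of -0.14 with 15 of 22 members below 0 (camera adjusted p of 0.0220, and adjusted p = 0.433 with an estimated correlation). Its most highly expressed members Sod2 and Vcam1 had 0.01 and -0.31, the sign of Sod2 turning with the setting, and Tlr2, a receptor of bacterial lipoproteins and the 1 member that was lower when adjusted over the list alone, had -1.26. The cytokine call was lost without shScr library 2 (camera adjusted p of 0.0869) or shFabp7 library 2 (0.0914) and with the stricter filter (0.388), where its mean difference of -0.52 in log2 CPM was -0.41, -0.44 and -0.27. The NF-kB call was lost without shScr library 2 (0.187) or 3 (0.0520), where its mean difference of -0.19 was -0.17 and -0.19.

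Interferon-stimulated genes had a median of -0.30, with 24 of 30 members below 0 and 0 past the threshold, over all genes or over the list alone. Stat2 and Ifi27, the most highly expressed, had log2 fold changes of 0.10 and 0.02, the sign of Ifi27 turning with the setting, while Ifit1 and Ifitm3, antiviral effectors, had -0.71 and -0.65. Camera gave an adjusted p of 0.000203, and adjusted p = 0.579 with an estimated correlation. Genes of MHC and antigen presentation had a median of -0.29, with 14 of 17 below 0 and 0 past either threshold (camera adjusted p of 0.0102, and adjusted p = 0.505 with an estimated correlation). B2m and H2-K1 had -0.08 and -0.14, the sign of B2m turning without shScr library 3. Complement genes had a median of -0.27, with 10 of 14 below 0 and 4 lower when adjusted over the list alone (camera adjusted p of 0.0105, and adjusted p = 0.505 with an estimated correlation). C4b averaged 90.5 ± 14.8 CPM in shScr and 52.7 ± 10.2 CPM in shFabp7, a log2 fold change of -0.78, and C1qa and Clu had -0.34 and -0.18. Reads of Serpina3n, C4b, H2 and ribosomal protein genes can be shared with near-identical copies, so their values are uncertain. Without shScr library 3 the MHC and complement calls were lost (camera adjusted p of 0.0520 each), with mean differences in log2 CPM of -0.23 in place of -0.28 and -0.14 in place of -0.18, and the mean difference of the interferon list in log2 CPM was -0.20 in place of -0.32. The MHC call was also lost without shScr library 2 (0.0622), with a mean difference of -0.27.

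Homeostatic microglia markers had a median of -0.17, with 14 of 18 below 0 and 5 lower when adjusted over the list alone (camera adjusted p of 0.00652, and adjusted p = 0.553 with an estimated correlation). Csf1r, a growth factor receptor of microglia, had a log2 fold change of -0.07. Its sign turned with the regional score or without shScr libraries 1 and 3. Olfml3 had -0.56 and Itgam, an integrin of myeloid cells, -0.54. Itgam shares 68.7% of its exon sequence with Gm49368 on the same strand, so its value is uncertain. Astrocyte markers as a list were not called: their median was 0.03 and their mean -0.02, 10 of 18 were above 0, and camera, whose direction was up, gave an adjusted p of 0.862. Gfap, which is also on this list, was its 1 member lower when adjusted over the list alone. The glutamate transporter genes Slc1a2 and Slc1a3 had 0.18 and -0.16. Over the alternatives they ranged from 0.030 to 0.26 and from -0.20 to -0.097. Genes of astrocyte glutamate, potassium and water handling had a median of -0.0012, a mean of 0.03 and a camera adjusted p of 0.395 with the direction up. Adjusted over the list alone, 3 were higher and 1 lower. Glul, glutamine synthetase, averaged 1605 ± 68.9 CPM in shScr and 2012 ± 71.5 CPM in shFabp7, a log2 fold change of 0.33. Kcnj10, a potassium channel, had 0.38, and Aqp4, the water channel, had -0.34. The Aqp4 value ranged from -0.44 to -0.10 over the alternatives.

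Immediate-early genes, which neurons and glia switch on within minutes of stimulation, were called lower, with a median of -0.51 and 19 of 22 members below 0. Camera gave the list an adjusted p of 3.88e-05, and adjusted p = 0.579 with an estimated correlation. Their mean log2 CPM was 4.86, 5.69 and 5.41 in shScr libraries 1 to 3 and 4.89, 4.66 and 4.80 in shFabp7 libraries 1 to 3, so shScr library 1 lay within the shFabp7 range. The mean difference of -0.54 became -0.35 without shScr library 2 and -0.89 with the regional score, and the call at the preset correlation held in both. Fos passed over all genes tested, and 8 members were lower when adjusted over the list alone. Among these, Nr4a3 had a log2 fold change of -1.74, Fosl2 -1.17, Egr2 -1.15 and Junb -0.77. The list of glucocorticoid-responsive genes was called higher, with a median of 0.20 and 12 of 16 members above 0 (camera adjusted p of 0.0105, and adjusted p = 0.602 with an estimated correlation). Adjusted over the list alone, 5 were higher, and 0 of the 16 passed over all genes tested. Plin4, a lipid droplet coat protein, averaged 9.96 ± 1.98 CPM in shScr and 30.9 ± 10.01 CPM in shFabp7, a log2 fold change of 1.63. Hif3a had 0.78, Tsc22d3, which encodes the anti-inflammatory protein GILZ, had 0.48, and the most highly expressed members Klf9 and Per1 had 0.49 and -0.12, the sign of Per1 turning without shScr library 2. The glucocorticoid call was lost without shScr library 3 (camera adjusted p of 0.0520), shFabp7 library 3 (0.124) or shScr libraries 1 and 3 together (0.346), where its mean difference of 0.29 was 0.27, 0.20 and 0.18.

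Camera called the list of synaptic genes higher and that of ribosomal protein genes lower at its preset correlation, and neither with an estimated one (adjusted p = 0.553 and adjusted p = 0.579). The synaptic list had a median of 0.17, with 24 of 30 members above 0, 0 past the threshold over all genes and 1, Shank3 at 0.34, higher when adjusted over the list alone (camera adjusted p of 0.000139). Camk2a and Snap25 had 0.37 and 0.43, and ranged from 0.16 to 0.44 and from 0.13 to 0.56 over the alternatives. The synaptic call was lost with the regional score (0.0615), where its mean difference of 0.17 in log2 CPM became 0.060, and that difference was 0.11 without shScr library 1 or without shScr libraries 1 and 3. All 40 cytosolic ribosomal protein genes had values below 0, with a median of -0.13, 0 past either threshold and examples Rpl3 at -0.22 and Rpl4 at -0.09 (camera adjusted p of 8.38e-07). Excitatory neuron markers had a median of 0.40, with 13 of 16 above 0 and 0 past either threshold (camera adjusted p of 0.00652, and adjusted p = 0.553 with an estimated correlation). Their mean log2 CPM was 6.16, 6.84 and 6.59 in shScr libraries 1 to 3 and 6.87, 6.98 and 6.87 in shFabp7 libraries 1 to 3, and the mean difference of 0.38 became 0.20 without shScr library 1. The call was lost with the regional score (camera adjusted p of 0.258), which itself holds these markers, and without shScr libraries 1 and 3 (0.205), where the mean difference was 0.037 and 0.071. Slc17a7, the cortical glutamate transporter of synaptic vesicles, had 0.24, and -0.033 with the regional score.

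**Figure D3:**
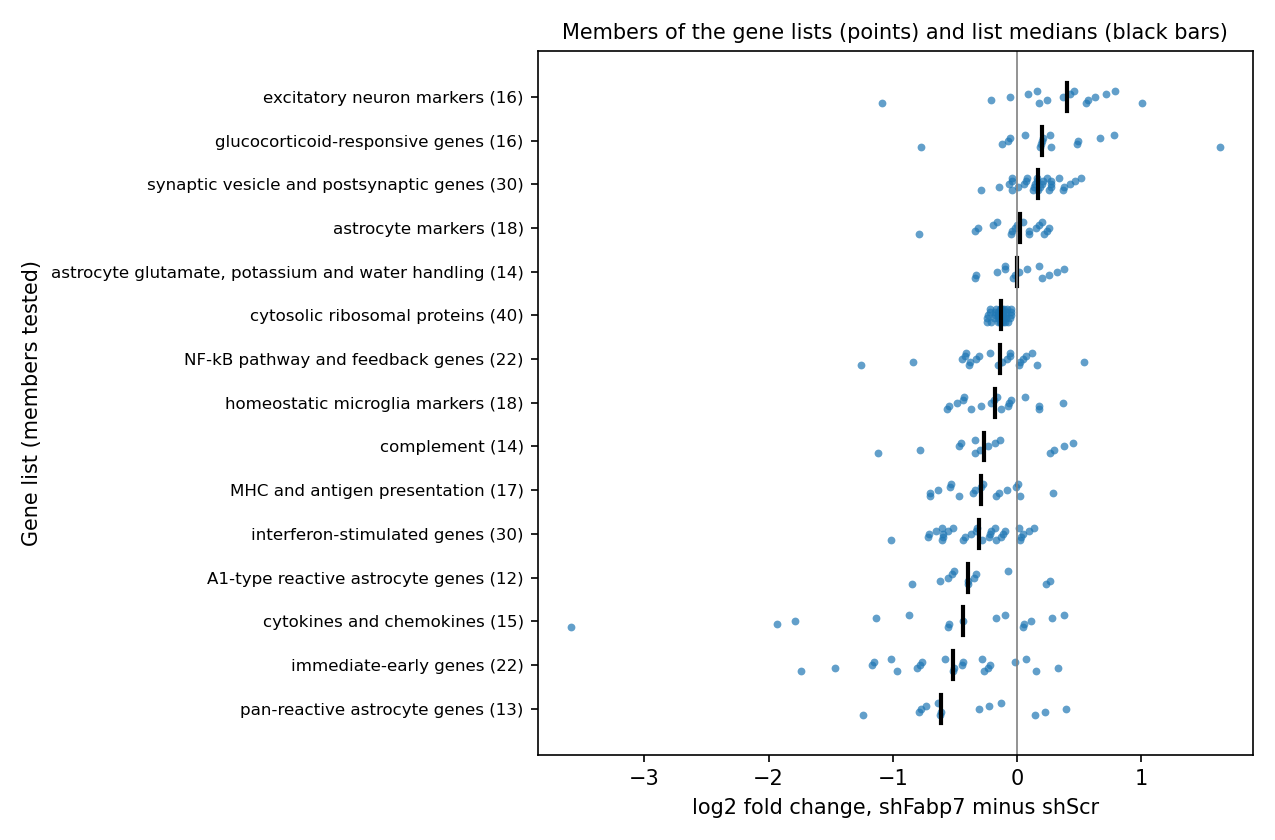
Log2 fold changes, shFabp7 minus shScr (horizontal axis), of the members of 15 gene lists (rows, with the number of members tested); points are genes and black bars list medians. The medians run from -0.61 for pan-reactive astrocyte genes to 0.40 for excitatory neuron markers, with astrocyte markers at 0.03.

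Of the 43 lists tested, camera called 22, 5 higher and 17 lower. With an estimated correlation 0 were called and 3 had an unadjusted p under 0.05, and fry called 0 after adjustment with 15 at an unadjusted p under 0.05. Marker lists of some other brain regions were called lower, with 0 of 9 hippocampal and 0 of 10 ependymal and choroid plexus members past the threshold over all genes: hippocampal neuron markers had a median of -0.59 (camera adjusted p of 0.0270, and adjusted p = 0.602 with an estimated correlation), and ependymal and choroid plexus markers -0.57 (camera adjusted p of 0.0106, and adjusted p = 0.553 with an estimated correlation). Striatal markers (median -0.10, mean -0.23, camera adjusted p of 0.628) were not called. Nor were thalamic and hypothalamic markers (median -0.18, mean -1.08, camera adjusted p of 0.347). Striatal markers had a mean log2 CPM of 6.06, 4.73 and 5.21 in shScr libraries 1 to 3. In shFabp7 libraries 1 to 3 it was 4.73, 4.19 and 6.07, so shFabp7 library 3 was as high as shScr library 1. Thalamic and hypothalamic markers had 3.51, 2.72 and 1.902 in shScr and 2.07, 2.08 and 1.99 in shFabp7. High values of these markers were therefore not confined to shScr libraries 1 and 3. Hippocampal markers had a mean log2 CPM of 3.35, 2.94 and 4.49 in shScr libraries 1 to 3 and 2.93, 2.54 and 2.79 in shFabp7 libraries 1 to 3. Their call was lost without shScr library 3 (0.148), where the mean difference was -0.39 in place of -0.84, without shFabp7 library 2 (0.0574) or 3 (0.0577), with the regional score, of which they are a part (0.124), and without shScr libraries 1 and 3 (0.986). The mean difference was -0.73 and -0.86 without shFabp7 libraries 2 and 3, -0.72 with the regional score and -0.18 without shScr libraries 1 and 3. The ependymal and choroid plexus call was lost without shScr library 3 (0.0577), with the regional score (0.112) and without shScr libraries 1 and 3 (0.315), where its mean difference of -0.78 was -0.64, -0.52 and -0.44. The regional score was -1.70, -3.28 and -2.75 in shScr libraries 1 to 3 and -3.55, -3.97 and -3.10 in shFabp7 libraries 1 to 3. Counts of sex-linked genes marked 2 male and 1 female shScr libraries, and 1 male and 2 female shFabp7 libraries. The Y-linked gene Ddx3y had 1362, 1299 and 16 reads in shScr libraries 1 to 3 and 1105, 71 and 15 in shFabp7 libraries 1 to 3, so shFabp7 library 2 had more than the other 2 libraries read as female.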

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

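Sex, the regional score and the pair of shScr libraries left out were chosen after the data were seen, and the other alternatives before. Numbers of genes are given as total, higher and lower. Against 20 (10 and 10), DESeq2 called 699 (386 and 313), no filter 1617 (793 and 824), limma-voom with quality weights 109 (65 and 44), 1 surrogate variable 1399 (805 and 594) and a threshold of 0.1 called 292 (158 and 134). Sex as a covariate gave 7 (1 and 6), 4 of them among the 20. The regional score as a covariate gave 9 (4 and 5), 7 of them among the 20, and both shScr libraries 1 and 3 left out gave 89 (29 and 60), 15 of them among the 20. With both left out, 1 shScr library stands against 3, the spread comes from the shFabp7 libraries alone, and the lone library is assumed to vary like them. RLE factors, upper-quartile factors and the stricter filter gave the same 20 genes. Leaving out 1 library gave 0 to 900 genes, 0 to 504 higher and 0 to 396 lower. The count was 0 without shFabp7 library 2 (1714 at an unadjusted p under 0.05) or 3 (2170), and 900 without shScr library 2. The cause was not tested.

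Fabp7 was lower under each of the 17 alternatives, with log2 fold changes from -2.66 to -1.78 and adjusted p from 3.41e-12 to 0.337. It passed the threshold with DESeq2 (-2.30), no filter (-2.31), limma-voom (-2.28), the replicate block (-2.32), 1 surrogate variable (-2.26) and without shScr library 1 (-2.004) or 2. Leaving out 1 library gave -2.66 to -2.004. It did not pass with sex (-2.14), the regional score (-1.78) or both shScr libraries left out (-1.97).

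With the replicate number as a block, 629 genes passed (350 higher and 279 lower) and 21 lists. The numbers were not taken to pair the samples, since no label says that they mark a litter, batch or day. Same-numbered libraries correlated at 0.08, 0.15 and 0.06 in their deviations from the group means, and differently numbered ones at -0.18 to 0.10. For shScr libraries 2 and 3 the same-numbered library correlated best. For shScr library 1 it was shFabp7 library 3 (0.10). These correlations are small and do not settle whether the samples are paired.

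Of the 22 lists called, the correlation estimated per list left 0 (0 higher and 0 lower), and fry 0 (0 and 0). The stricter filter left 19 and sex 20. The regional score called 15 lists (3 higher), 14 of them among the 22, and both shScr libraries left out 17 (2 higher), also 14 of them among the 22. Leaving out 1 library gave 14 (without shScr library 3, 12 of them among the 22) to 21 lists, 3 to 5 higher and 10 to 16 lower. No called list changed direction.

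Some values that were not called by the main test changed sign. With limma-voom Fabp5 had -0.018 and Ifi27 -0.0079. With sex Fabp5 had -0.0074 and Ifi27 -0.050. With the regional score Fabp5 had -0.0071, Sod2 -0.026, Csf1r 0.036 and Slc17a7 -0.033, and with both shScr libraries left out Sod2 had -0.0066 and Csf1r 0.0016. Leaving out 1 library gave -0.057 to 0.087 for Fabp5, -0.21 to 0.040 for H2-D1, -0.027 to 0.039 for Sod2, -0.058 to 0.14 for Ifi27, -0.20 to 0.023 for B2m and -0.19 to 0.013 for Per1. The cause was not tested. The median of all genes stayed within 0.02 of 0 in each setting. At these depths, genes such as Il1b, with 1 read in each shFabp7 library, have wide intervals.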

Other observations

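Tests of sex, region and the shares of astrocytes and microglia, and the counts over other splits, were chosen after the results were seen, and those of gene length and GC content before. Ighm, the immunoglobulin heavy chain gene of B cells, averaged 14.2 ± 3.31 CPM in shScr and 32.6 ± 7.17 CPM in shFabp7 (SD, n = 3 each), higher in all 3 shFabp7 libraries. Its log2 fold change was 1.19, with an adjusted p of 0.0833 in edgeR and 1.16e-06 in DESeq2. The lymphocyte list it belongs to had only 3 members with enough counts and was not tested. Circadian clock genes had a median of 0.12, with 13 of 17 above 0 and Per3 at 0.50 (camera adjusted p of 0.0336, and adjusted p = 0.620 with an estimated correlation). Heat shock and unfolded protein response genes had a median of 0.08, with Manf, a secreted factor of endoplasmic reticulum stress, at 0.29 (camera adjusted p of 0.00890, and adjusted p = 0.621 with an estimated correlation). The acute-phase gene Saa3 had -2.14, and Cd109, a member of the A2-type astrocyte list, -1.41. The circadian call was lost without shScr library 1 (camera adjusted p of 0.183) or 3 (0.0809), without shFabp7 library 2 (0.0509) or 3 (0.105), with sex (0.0531) or the regional score (0.503) and without shScr libraries 1 and 3 (0.868). Its mean difference of 0.14 in log2 CPM was 0.13 with sex, 0.088 without shScr library 1, 0.043 with the regional score and 0.015 without shScr libraries 1 and 3. The heat shock call was lost without shScr library 2 (0.0749) or shFabp7 library 1 (0.0746), and its mean difference of 0.11 was 0.089 and 0.074 in these settings. Ighm, Per3, Manf, Saa3 and Cd109 were chosen after their values were seen.

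Lists called lower and not described so far were neural stem cell and developing glia markers (median -0.17), proliferation markers (-0.34), fibroblast and meningeal markers (-0.28), activated microglia markers (-0.15) and activated endothelial genes (-0.14), with camera adjusted p of 0.0102, 0.0106, 0.0123, 0.0360 and 0.0453. With an estimated correlation their adjusted p were 0.433, 0.433, 0.631, 0.433 and 0.433. The activated endothelial call was lost without shScr library 2 (0.162) or 3 (0.0784), without shFabp7 library 1 (0.0595) or 3 (0.146), with the stricter filter (0.0786), with the replicate block (0.107) and with sex (0.0514). Its mean difference of -0.19 in log2 CPM ranged from -0.22 to -0.14 over these settings, and was -0.31 with the regional score. The activated microglia call was lost without shScr library 1 (0.0902) or 3 (0.0836), without shFabp7 library 2 (0.0772), with the stricter filter (0.0655), with the regional score (0.163) and without shScr libraries 1 and 3 (0.315), and its mean difference of -0.19 was -0.11 and -0.080 in the last pair of settings. The fibroblast and meningeal call was lost without shScr library 3 (0.0985) or shFabp7 library 3 (0.132), with the regional score (0.112) and without shScr libraries 1 and 3 (0.830), and its mean difference of -0.32 was -0.20 and -0.044 in the last pair of settings. The proliferation call was lost with the regional score (0.0649) and without shScr libraries 1 and 3 (0.0609), and its mean difference of -0.32 was -0.23 and -0.28 in these settings. Lists of lipid metabolism were not called: medians were -0.06 for cholesterol biosynthesis, -0.0031 for fatty acid synthesis, -0.07 for fatty acid oxidation and PPAR targets and -0.07 for lipid droplets and transport. The mean was 0.0064 for the lipid droplet list, where camera's direction was down, and 0.03 for fatty acid synthesis, where it was up, so median and mean differed in sign in both. Myelin genes had a median of 0.06 and a mean of -0.0015, with camera's direction up. Oligodendrocyte, myelin, oligodendrocyte precursor, endothelial, pericyte and smooth muscle, inhibitory neuron, striatal, thalamic and hypothalamic, erythroid and border macrophage lists were not called either. Nor were the lists of glycolysis, NRF2 targets, nuclear oxidative phosphorylation and mitochondrially encoded genes.

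Genes of other brain regions differed between libraries. Avp, the vasopressin gene of the hypothalamus, had 715, 92 and 9 reads in shScr libraries 1 to 3 and 14, 5 and 4 in shFabp7 libraries 1 to 3. Dsp, a gene of dentate gyrus granule cells, had 17, 9 and 157 reads in shScr and 14, 2 and 10 in shFabp7. C1ql2, also of the dentate gyrus, had 114, 111 and 319 reads in shScr and 10, 10 and 17 in shFabp7. Ndst4, which is on none of the marker lists and was not assigned to a region here, had 979, 688 and 254 reads in shScr. It had 47, 22 and 30 in shFabp7. These genes were chosen after their values were seen. Xist had 58, 44 and 17145 reads in shScr libraries 1 to 3 and 70, 12643 and 17866 in shFabp7 libraries 1 to 3.

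The mean log2 CPM of 70 genes of the pan-reactive, A1-type, cytokine and interferon lists was lower in shFabp7 by -0.37 ± 0.06 (SE). These 4 lists had been called lower in the same libraries, and the A2-type list, which was not called, was left out. The size of this difference is therefore not separate evidence that the lists were lower. The difference was -0.37 ± 0.07 with sex in the model, which argues against sex imbalance as the whole cause, and 17 astrocyte markers without Gfap differed by 0.022 ± 0.024 where the pan-reactive genes differed by -0.37 ± 0.07, which argues against a lower share of astrocytes. With the regional score in the model the difference was -0.34 ± 0.08, less than 2 SE beyond 50% of the unadjusted value. Camera at its preset correlation still called 4 of the 4 lists lower, while the synaptic list went from 0.17 to 0.060. With estimated correlations, in the model without the score, camera called 0 lists. The score missed some regional signal. It was -3.28 in shScr library 2, within the shFabp7 range of -3.97 to -3.10. That library had 92 Avp and 111 C1ql2 reads, against 14, 5 and 4 and 10, 10 and 17 in shFabp7. The score therefore cannot settle whether tissue of other regions in the shScr samples is the whole cause or a part, and both stay open. A lower share of microglia stays open too: 18 homeostatic microglia markers differed by -0.18 ± 0.05. That lies within 2 SE of 50% of the unadjusted difference. A candidate explanation that also stays open is an effect of the Fabp7 shRNA on the response to LPS, which was not tested against samples without LPS.

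The ribosomal protein list had a median of -0.13. After the trend of log2 fold change on exon length was removed the median was -0.12 ± 0.01 (SE). After that on transcript GC content (known for 17134 of the 17185 genes) it was also -0.12 ± 0.01. These SEs are over the 40 genes taken as independent, whose estimated correlation was 0.58, so they do not measure the spread between libraries. Both trends were small over all genes. Medians in 5 bins of genes ran from -0.015 to -0.0015 by length and from -0.024 to 0.0099 by GC content. Neither trend therefore accounts for the difference. Other technical causes and an effect of the shRNA may both play a part and were not tested.

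The lower level of Fabp7 stayed beyond 50% of its unadjusted log2 fold change of -2.31 ± 0.35 (SE), by more than 2 SE, in both models with a covariate. It was -2.14 ± 0.27 with sex, which argues against sex imbalance as the whole cause. It was -1.78 ± 0.30 with the regional score, which missed regional signal in shScr library 2, so tissue of other regions stays open. Knockdown by the shRNA remains a candidate explanation, as a hypothesis from the same data.

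The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes past the threshold, 1 of the 10 splits, the real one, reached 20, and the highest of the others was 2, in the split of males against females. For lists past the threshold, 1 of the 10 splits, the real one, reached 22, and the highest of the others was 14.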
